A study of Mus musculus with 8 samples.

How the data were processed

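The samples were mouse bone marrow cells grown in culture from wild-type animals and from animals lacking miR-223, a microRNA made mainly in myeloid cells. Day 4 samples were progenitors, kept 4 days with granulocyte colony-stimulating factor (G-CSF, which drives granulocyte formation) and stem cell factor (SCF, the ligand of c-Kit) and sorted as c-Kit positive and Gr-1 negative. Day 8 samples were mature neutrophils, kept 6 days with both factors and 42 hours without SCF, and sorted as c-Kit negative and Gr-1 positive. Each of the 4 combinations of genotype and day had 2 arrays, 8 in all, each hybridized with biotin-labelled material made from total RNA. The labels do not say whether the 2 replicates of a group came from separate animals or cultures, so every p-value here measures the spread between arrays and not necessarily that between animals.

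The deposited table held 1 value per array for 45101 Affymetrix probe sets, of which 64 were control probe sets. The values deposited by the authors are on a log2 scale. The log base was read from the values, since the labels do not state it. GCOS, the scanner software, is named in the submitters' processing notes without a version. The method that summarized probes into probe sets, the background correction and the normalization between arrays are not given in the sources used here. The 8 medians lay within 0.054 of each other, so the table was taken as already normalized and analysed as deposited. A background correction that pulls dim probe sets towards a floor would change fold changes of transcripts that are near background in 1 group, and a normalization that equalizes arrays would remove any change in total messenger RNA per cell between days or genotypes.

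Neither the table nor the gene reference at hand (RefSeq genes of mouse) pairs the probe set identifiers with genes: 0 of the identifiers were found in the reference. Each probe set was therefore its own feature, and no gene name was inferred from an identifier. Only the mouse control probe sets name a transcript (beta-actin, Gapdh, transferrin receptor, pyruvate carboxylase, 18S ribosomal RNA, and the B1 and B2 repeats), and these 19 probe sets were fitted together with the tested ones. Without that pairing the 24 gene lists fixed beforehand, including earlier named miR-223 targets, granule genes and markers of other cell types, could not be tested. The tests of miR-223 seed sites in 3' untranslated regions and the rank of the seed among all words were not run, since no transcript sequence was given either. The absence of miR-223 from the null arrays could not be checked, because no probe set could be assigned to its gene.

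Probe sets with a mean over all arrays at or above the median of the 45037 probe sets without controls (5.51 on the log2 scale) were tested, which left 22519. One linear model with the 4 group means was fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, leaving 4 residual degrees of freedom. The 5 comparisons were null against wild type on each day, day 8 against day 4 in each genotype, and the difference between the days in the null effect (the interaction term). All tests were two-sided. Adjusted p is the Benjamini-Hochberg value over the probe sets tested within a comparison, and a probe set was called at an adjusted p below 0.05. Log2 changes are given with the model's standard error (SE), and group means with the standard deviation (SD) of 2 arrays. With 2 arrays against 2, an exact permutation test of a single probe set cannot give a p below 0.333, so all calls rest on the spread that limma shares across groups and probe sets. The comparisons, the filter, the threshold, the alternatives other than those named below as added, and the rule for named features were fixed before the data were examined. For arrays, their number limits the precision: the median SE of a log2 change between 2 groups was 0.115, and that of the interaction was 0.163.

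That rule took, per comparison and direction, the called features with the largest log2 change. In the comparisons of 2 groups, but not in the interaction, their arrays also had to be without overlap between the groups. It had allowed 8 per direction, but since identifiers without a gene name say little, only the first 2 per direction are given. The same steps were tested on simulated data with 100 probe sets changed by 0.5 and 100 changed by 1 on the log2 scale: 99% or more of the changes of 1 were called in the comparisons of 2 groups and 88% in the interaction. Of the changes of 0.5, between 41% and 68% were called in the comparisons of 2 groups and 21% in the interaction. Between 6 and 13 of 22319 unchanged probe sets were called in a comparison. The simulated errors were independent, and each probe set had the same spread in all 4 groups. These rates therefore do not cover errors shared across an array or groups of unequal spread, and are not error rates of the calls reported below.

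The alternatives were quantile normalization, scaling to the same median, cyclic loess, no filter, a filter at the 75th percentile, no intensity trend, a fit of only the groups compared, the replicate number as a block, array weights, an adjusted p below 0.10, a change of at least 1.5-fold, and leaving out each array in turn. Scaling each array to its 18 bacterial and phage hybridization controls, which the standard protocol adds to the hybridization mix after labelling, and the fit of the mouse control probe sets were added after the data had been seen. Alternatives for choices that did not arise (a pseudocount, another way to combine probe sets of a gene) were not run. Figures were drawn from the same values.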

Results

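Gene expression was measured in cultured mouse bone marrow cells at 2 stages of neutrophil formation, the c-Kit positive progenitor at day 4 and the Gr-1 positive mature neutrophil at day 8, with and without miR-223. Each of the 4 groups had 2 arrays. The arrays separated mainly by day: the first principal component of the 22519 tested probe sets held 94.8% of the variance and the second, which parted the genotypes, 1.95%. Wild-type day 4 arrays lay at -84.2 (replicate 1) and -95.1 (replicate 2) on the first component and null day 4 arrays at -98.6 and -100.5, with day 8 arrays at 90.9 to 100.5. Across probe sets, replicates of a group correlated at 0.993 to 0.997 (Pearson's r), and the highest correlation of any array with an array of another group was 0.992. The spread of the replicate differences was largest in wild-type day 4 cells (SD 0.229 on the log2 scale) and smallest in null day 4 cells (SD 0.158).

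The change from progenitor to mature neutrophil was first followed in wild-type cells. Transferrin receptor, which brings iron into dividing cells, fell 5.26-fold at its 3' control probe set, from 8.70 ± 0.20 at day 4 to 6.31 ± 0.25 at day 8 (log2 mean ± SD, n = 2; log2 change -2.40, SE 0.16, adjusted p = 1.3e-07). Its middle and 5' probe sets fell 4.57-fold and 5.09-fold. Transcripts that carry the B1 repeat, a short interspersed element found in many mouse RNAs, fell by 0.89 on the log2 scale (SE 0.06, adjusted p = 1.9e-07). Of the 22519 probe sets tested, 17374 (77.2%) were called, 7985 higher and 9389 lower at day 8, and 2823 rose and 4665 fell by at least 2-fold.

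At the far end of that range, 114 probe sets rose and 79 fell by 16-fold or more. The largest rises were those of 1448573_A_AT, from 5.08 ± 0.28 to 12.43 ± 0.06 (SD, n = 2; log2 change 7.35, SE 0.12, adjusted p = 1.3e-11), and of 1450808_AT, by 7.22 (SE 0.10). The day 4 means of both lay below the filter value of 5.51, taken as near background, so the size and rank of these rises depend on the authors' background correction. The largest falls were those of 1433575_AT, from 11.33 ± 0.02 to 4.15 ± 0.45 (SD, n = 2; log2 change -7.18, SE 0.23, adjusted p = 6.3e-10), and of 1454269_S_AT, from 9.68 to 3.53. The files do not pair these identifiers with genes. The day 8 means of these falls, 4.15 and 3.53, lay near the lower quartile of the arrays (3.83 to 4.00), so the same limit holds for the falls.

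The same change was followed in null cells. Transferrin receptor fell 6.78-fold at its 3' probe set, from 9.04 ± 0.18 to 6.28 ± 0.22 (SD, n = 2; log2 change -2.76, SE 0.16, adjusted p = 3.6e-08), and 5.04-fold and 5.75-fold at its middle and 5' probe sets. B1 repeat RNA fell by 1.07 on the log2 scale (SE 0.06). In null cells 17085 probe sets (75.9%) were called, 8106 higher and 8979 lower at day 8, with 3278 rises and 4508 falls of at least 2-fold. The largest rises were those of 1419709_AT (log2 change 7.70, SE 0.08) and 1448573_A_AT (7.67, SE 0.12), and the largest falls those of 1433575_AT (-6.84, SE 0.23) and 1422873_AT (-6.17, SE 0.26), each with 2 arrays per group and an adjusted p of 3.4e-09 or less. Both falls, and the rise of 1448573_A_AT from a mean of 4.71, again had a mean near background, so their size and rank depend on its correction.

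The changes in both genotypes were compared probe set by probe set on separate arrays. They correlated at r = 0.978 (Spearman's rho = 0.968) across the 22519 probe sets, which are not independent replicates, with a slope of 1.02 for null on wild type. In both genotypes 7045 probe sets were called higher at day 8 (2874 if the calls were independent) and 8507 lower (3744 if independent), while 3 were called higher in wild type and lower in null and 34 the reverse. The direction of a change of this breadth is relative to the scaling. Scaled to the hybridization controls, the median of all probe sets moved to -0.21 in wild type and -0.35 in null, against -0.04 and 0.00 as deposited. The share of calls that were higher went from 46.0% to 36.1% in wild type and from 47.4% to 29.9% in null.

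**Figure D1:**
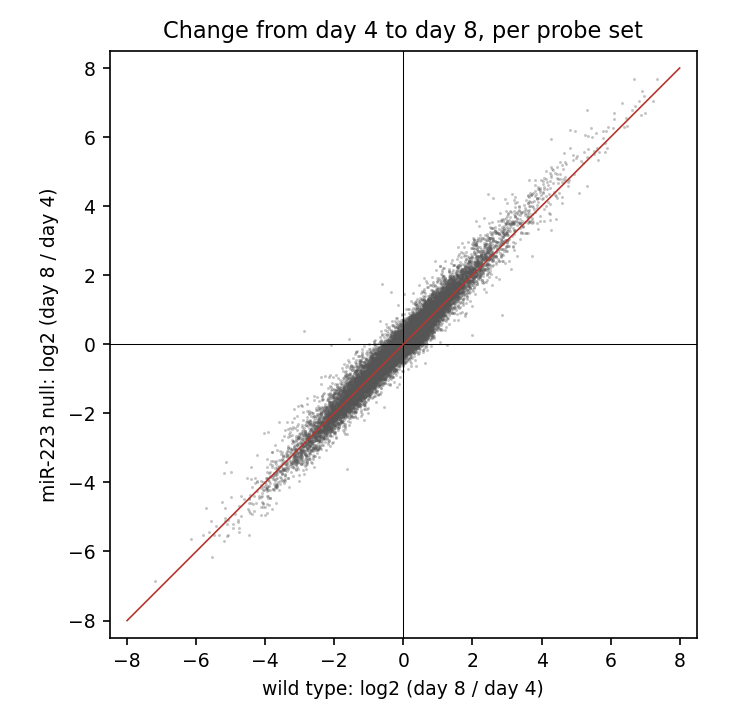
Log2 change from day 4 to day 8 in wild-type cells (horizontal axis) and in miR-223 null cells (vertical axis), 1 point per tested probe set, 22519 in all, each from the means of 2 arrays per group. The line marks equal change, and the points follow it closely (r = 0.978 across probe sets).

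The other control transcripts were followed over maturation as well. Beta-actin rose by 0.28, 0.47 and 0.55 on the log2 scale at its 3', middle and 5' probe sets in wild type. The rises in null were 0.19, 0.40 and 0.46, but scaled to the hybridization controls the 3' probe set of the null turned to -0.16 and only the middle and 5' probe sets of wild type were still called. The call of the 3' probe set in null was also lost after quantile normalization (log2 change 0.10, adjusted p = 0.081). Gapdh, a glycolytic enzyme, rose by 0.13 to 0.20 at its 3 probe sets in wild type and by 0.15 at the 5' probe set in null, but under that scaling none of these 4 changes was called and 3 turned negative. The 3' and middle probe sets of Gapdh in null, not called as deposited, were called lower under that scaling (-0.26 and -0.25) but higher after quantile normalization (0.15 and 0.19) and cyclic loess (0.27 and 0.29). The Gapdh calls at the 3' and middle probe sets of wild type were also lost without wild-type day 8 replicate 1 (log2 changes 0.15 and 0.12) or wild-type day 4 replicate 2 (0.10 and 0.11), and that of the middle one after scaling to the same median (0.10, adjusted p = 0.068). The Gapdh call in null was lost without null day 4 replicate 2 (0.13) or null day 8 replicate 2 (0.12). Pyruvate carboxylase, a mitochondrial enzyme, rose at 2 of its 4 probe sets in wild type (by 0.47 and 0.49) and at 1 in null (by 0.52), but at none when scaled to the hybridization controls. The probe sets for the B2 repeat fell by 0.26 and 0.43 in wild type and fell by 0.30 and 0.62 in null, but after cyclic loess only those with the larger fall were called. Those for 18S ribosomal RNA were called lower at all 3 positions in wild type (-0.51 to -1.02) and at 1 in null (-0.79). In null the middle probe set (-0.38, adjusted p = 0.056) was called in 5 alternatives and the 3' probe set when scaled to the hybridization controls (-0.62). After quantile normalization the null call was lost (adjusted p = 0.055, highest over the alternatives 0.14), and so was that of the 3' probe set in wild type (-0.28, adjusted p = 0.11, highest 0.15). The 5' value in wild type was -1.61 without wild-type day 4 replicate 1 and -0.43 without replicate 2. The 3' value there was -0.79 without wild-type day 8 replicate 1. Without wild-type day 4 replicate 2 or wild-type day 8 replicate 2, the 3' probe sets of pyruvate carboxylase (0.25 and 0.43) and 18S ribosomal RNA (-0.42 and -0.24) were not called in wild type. The 5' probe set of 18S ribosomal RNA was not called in wild type without wild-type day 8 replicate 2 (-0.90). In null, the call of pyruvate carboxylase was lost without replicate 1 of either day (0.43 and 0.48), and that of 18S ribosomal RNA without null day 4 replicate 2 (-0.62) or either null day 8 array (-0.76 and -0.81). The log2 signal of beta-actin at the 3' over the 5' probe set, a sign of RNA integrity, was 0.36 to 0.44 on the day 4 arrays and 0.10 to 0.17 on the day 8 arrays. For Gapdh it lay between -0.08 and 0.05 on all 8 arrays. The larger rise of beta-actin towards its 5' end therefore cannot be told apart from a difference in RNA integrity or labelling between the days. Such a difference could also add to other changes from day 4 to day 8, although Gapdh did not show it.

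The genotypes were then compared within a day, to ask what the loss of miR-223 does to messenger RNA in mature neutrophils. At day 8, 921 probe sets were higher and 274 lower in null cells, 1195 in all or 5.31% of those tested. Most changes were small: the median called change was 1.42-fold in either direction, and 54 probe sets rose and 15 fell by 2-fold or more. The largest rise was that of 1427451_A_AT (4.30 ± 0.15 in wild type against 12.17 ± 0.13 in null, SD, n = 2; log2 change 7.87, SE 0.20, adjusted p = 1.4e-08). Its wild-type mean lay near the lower quartile of the arrays, so the size of the rise depends on the authors' background correction. The files give neither its gene nor its locus, so a difference in sequence between the strains or at the targeted allele is not excluded. The next largest rise was that of 1431249_AT, 6.85-fold (log2 change 2.78, SE 0.18, adjusted p = 3.8e-05, n = 2), from a wild-type mean of 5.34, near background, so the same limit holds.

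The largest falls at day 8 were those of 1455869_AT, from 7.28 ± 0.88 in wild type to 4.59 ± 0.01 in null (SD, n = 2; log2 change -2.69, SE 0.46, adjusted p = 0.0077), and of 1431213_A_AT (log2 change -2.18, or -1.42 without wild-type day 8 replicate 2, SE 0.54, adjusted p = 0.045). In both, the wild-type arrays differed widely from each other. The SE pools all 4 groups and so understates this spread, a limit that the adjusted p-values share. The null values of 1455869_AT lay below the filter value of 5.51, near background, so the size and rank of its fall depend on the background correction. The call of 1455869_AT was lost without null day 8 replicate 1 (adjusted p = 0.057) or wild-type day 8 replicate 2 (adjusted p = 0.082), in a range of 3.4e-06 to 0.082 over all alternatives. That of 1431213_A_AT was lost in 7 of 18 alternatives (range 0.00029 to 0.30): without wild-type day 8 replicate 2 or any 1 of the 4 null arrays, after scaling to the same median, and without the intensity trend. None of the 19 mouse control probe sets, transferrin receptor and beta-actin among them, was called by limma between the genotypes at day 8, and 0 had an unadjusted p below 0.05. Of the day 8 calls 77.1% were higher as deposited, but 67.8% after quantile normalization and 68.6% after cyclic loess. Scaled to the hybridization controls, 47.0% were higher (326 higher, 368 lower). The count of calls itself rested on single arrays: it was 355 without null day 8 replicate 1, 401 without wild-type day 8 replicate 2, 523 without null day 8 replicate 2 and 608 without wild-type day 8 replicate 1.

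The same contrast was made in progenitors. At day 4 the balance was the other way round: 131 probe sets were higher and 482 lower in null cells, 613 in all or 2.72% of those tested. Called changes were again small, with a median of 1.42-fold for rises and 1.46-fold for falls, and 13 rises and 48 falls reached 2-fold. The largest rise was again that of 1427451_A_AT, with the same limits (4.23 ± 0.54 against 11.14 ± 0.03, SD, n = 2; log2 change 6.91, SE 0.20, adjusted p = 5.7e-08). It was followed by 1445226_AT, which rose by 2.43 on the log2 scale (6.44 ± 0.27 against 8.87 ± 0.14, SD, n = 2; SE 0.18, adjusted p = 0.00013).

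The largest falls at day 4 were those of 1455869_AT, from 9.39 ± 1.14 to 4.61 ± 0.02 (SD, n = 2; log2 change -4.78, SE 0.46, adjusted p = 0.00058), and of 1438239_AT, from 8.42 ± 0.75 to 4.29 (log2 change -4.12, SE 0.27, adjusted p = 9.3e-05), which carried the same value on both null arrays. The null values of both were below 5.51, near background, so the size and rank of these falls depend on the background correction. Each SE pools all 4 groups, and the null day 4 arrays near background hardly varied. It therefore understates the spread of the wild-type day 4 arrays (SD 1.14 and 0.75), and the adjusted p-values have the same limit. Limma called none of the 19 mouse control probe sets at day 4, and 1 had an unadjusted p below 0.05. The share of day 4 calls that were higher was 21.4% as deposited, 29.6% after quantile normalization, 33.8% after cyclic loess. It was 51.9% (221 higher, 205 lower) after scaling to the hybridization controls. The count of calls was 217 without wild-type day 4 replicate 1 and 1674 (701 higher, 973 lower) without wild-type day 4 replicate 2. It was 129 and 140 without null day 4 replicate 1 and 2, and 397 and 401 without null day 8 replicate 1 and 2.

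**Figure D2:**
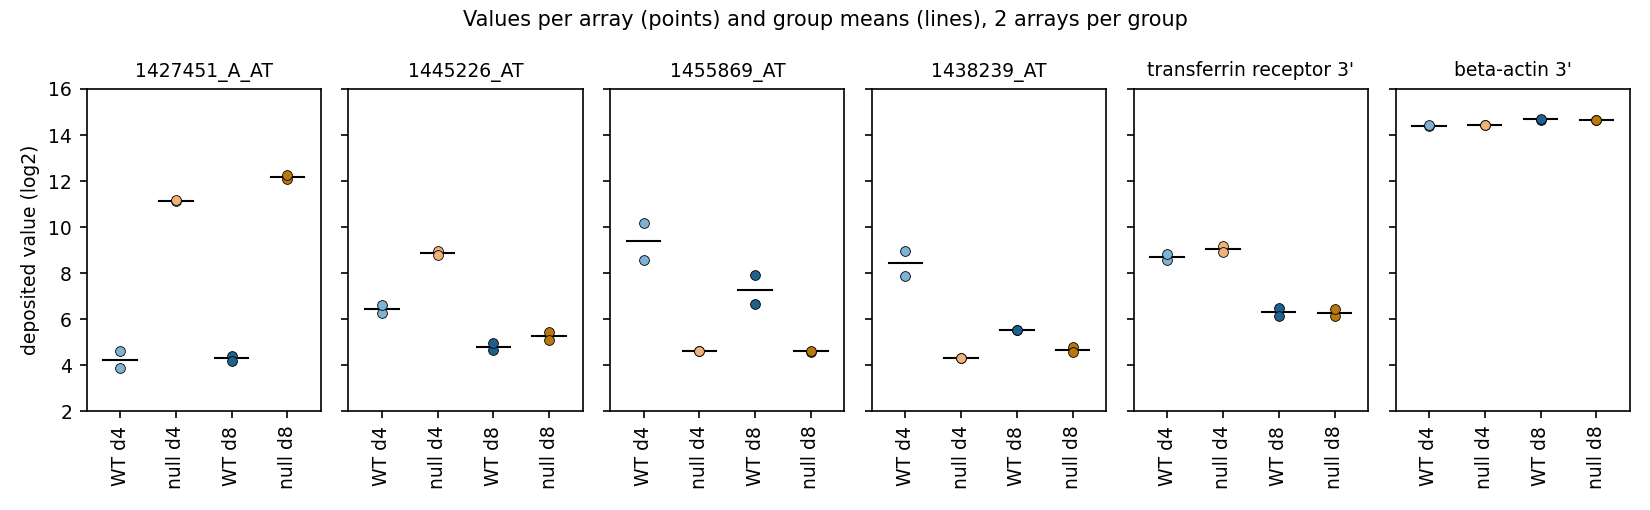
Deposited log2 value of 4 probe sets named for the null comparisons and of the 3' control probe sets of transferrin receptor and beta-actin, by group (WT, wild type; d4 and d8, days 4 and 8). Points are the 2 arrays of a group and lines their means: 1427451_A_AT had means of 4.23 and 4.30 in wild type and 11.14 and 12.17 in null, and transferrin receptor was lower at day 8 in both genotypes.

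Whether the genotypes differed in the same transcripts on both days was asked on arrays that the day 4 and day 8 contrasts do not share. Both contrasts used the same variance per probe set, so the counts given for independent calls are only a rough reference. A difference between the strains or at the targeted allele could also add to the overlap and is not excluded. Across the 22519 probe sets the null effects correlated at r = 0.283 (rho = 0.155), and at 0.187 with no filter on low values. There were 81 probe sets called higher on both days (5.36 if independent) and 51 called lower on both (5.86 if independent). Another 11 were called higher at day 8 and lower at day 4 (19.7 if independent), and 0 the other way round. Of the 131 probe sets higher in the null at day 4, 90.1% also had a positive change at day 8, against 54.9% of all tested probe sets, and of the 274 lower at day 8, 80.7% had a negative change at day 4, against 51.4%. For the larger sets these shares were 64.6% of the 921 higher at day 8 (48.6% of all tested) and 57.5% of the 482 lower at day 4 (45.1% of all tested), the latter with a median of -0.05 at day 8.

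**Figure D3:**
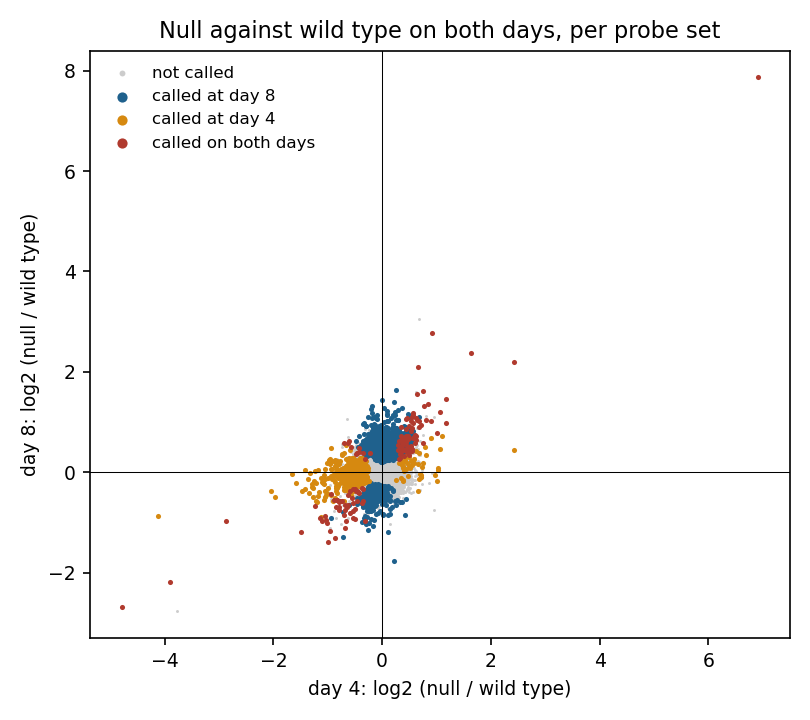
Log2 change of null against wild type at day 4 (horizontal axis) and day 8 (vertical axis), 1 point per tested probe set, from the means of 2 arrays per group. Colours mark calls at an adjusted p below 0.05: 81 probe sets were called higher and 51 lower on both days, and the point at the upper right is 1427451_A_AT.

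The difference between the days was then tested itself. The null effect was higher at day 8 than at day 4 for 348 probe sets and lower for 25. Of the 348, 182 were called higher at day 8 and not called at day 4, 112 were called lower at day 4 and not called at day 8, and 11 were called higher at day 8 and lower at day 4. The largest positive difference was that of 1438239_AT (log2 difference 3.25, SE 0.38, adjusted p = 0.0059, n = 2 per group), where the null mean at day 4 lay near background, so its size and rank rest on the background correction. It was followed by 1440370_AT (1.90, SE 0.29, adjusted p = 0.013, n = 2), with the same limit (null day 4 mean 5.27). Its call was lost in 6 of 18 alternatives (adjusted p from 0.00024 to 0.066), namely without any 1 of the 4 day 8 arrays, without null day 4 replicate 2, and without the intensity trend. The largest negative differences were those of 1419681_A_AT (-1.99, SE 0.23, adjusted p = 0.0059), which was lower in the null at day 8 and not called at day 4, and of 1445226_AT (-1.99, SE 0.25, adjusted p = 0.0066), higher in the null at day 4 and not called at day 8. Both genotypes had means near background on the day without a call (5.17 and 5.39 at day 4, 4.81 and 5.25 at day 8), so these sizes and ranks have the same limit.

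Scaling to the hybridization controls, which moved the median difference to -0.15, left 61 higher and 63 lower. Positive differences made up 93.3% of the calls as deposited, 88.6% after quantile normalization, 93.3% after scaling to the same median and 85.4% after cyclic loess. The count of calls was 48 to 94 when a null array or a day 8 array was left out, and 893 without wild-type day 4 replicate 2.

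**Figure D4:**
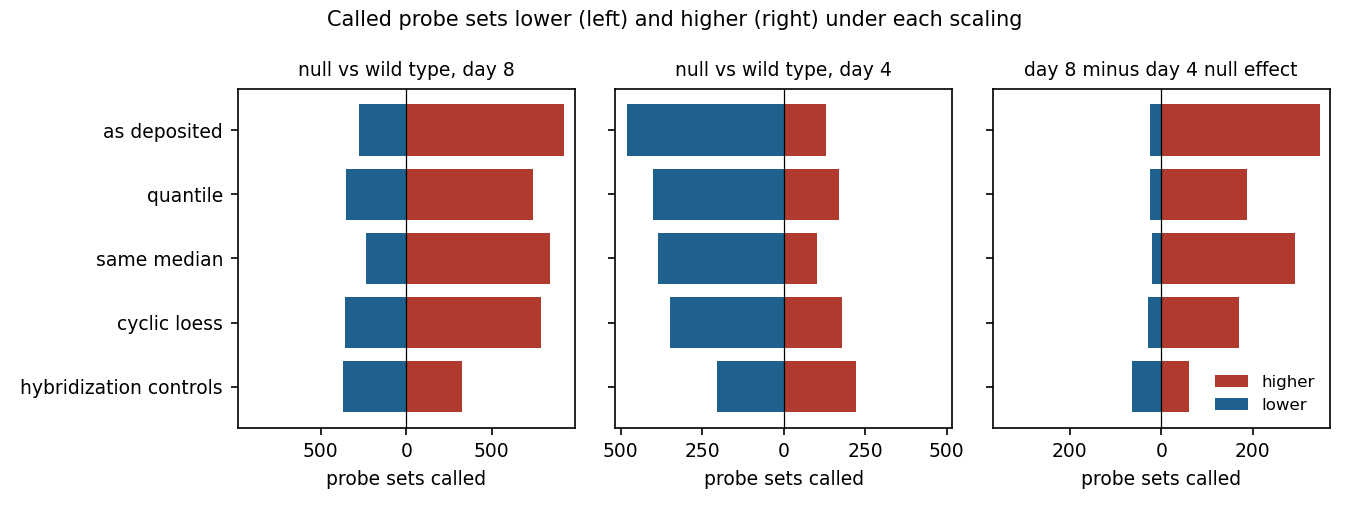
Probe sets called lower (bars to the left) and higher (bars to the right) under each scaling, for null against wild type at day 8, at day 4, and for the difference between the days, with 2 arrays per group. The split was 921 higher and 274 lower at day 8 as deposited and 326 and 368 after scaling to the hybridization controls.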

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

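Leaving out single arrays and the scalings other than that to the hybridization controls were planned, but their use as tests of an explanation, that scaling and the test of mature cells in the day 4 sort were chosen only after the results were seen, while the test by signal level was not.

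The null effect differed between the days, by the test of the difference itself, for 373 probe sets: it was higher at day 8 for 348 and lower for 25. The named ones among them were 1438239_AT, with a log2 difference of 3.25, 1440370_AT with 1.90, 1431249_AT with 1.86, 1419709_AT with 1.01, 1419681_A_AT with -1.99 and 1445226_AT with -1.99. All except 1419709_AT had a group mean below the filter value of 5.51, near background, so their sizes depend on the background correction. In 1438239_AT the null lay near background on both days, while the wild-type mean fell from 8.42 at day 4 to 5.54 at day 8. Both sides of the difference between the days were examined, the excess of probe sets lower in the null at day 4 and the excess of those higher in the null at day 8.

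At day 4, 482 of 613 calls were lower in the null. Without wild-type day 4 replicate 2 the share of lower calls was 58.1%, but lower calls rose to 973 and higher calls to 701, and without replicate 1 lower calls were 173 of 217, so this share does not decide what the spread between these arrays contributed. Mature cells carried into the wild-type sort would need a median share of 17.7% of the day 8 signal (quartiles 7.64% and 37.3%, 354 probe sets that were lower and rose with maturation), while the 100 probe sets with the largest rise showed a share of 3.77% (quartiles 1.15% and 8.71%). The 354 were chosen for their wild-type excess, which raises their share, and the 100 for their rise, which lowers theirs. The sets had 34 probe sets in common. The share of lower calls was 66.2% or more after quantile normalization, scaling to the same median and cyclic loess, and 48.1% when arrays were scaled to the hybridization controls. These controls were lower by 0.09 in the null, more than the SD between replicates (0.013 in wild type and 0.040 in null). That scaling still decides nothing, since it shifts all probe sets of an array alike and so moves the balance of calls by construction. A shift of 0.09 therefore cannot be told apart from an effect of the loss of miR-223. Nor can mature cells, since the 2 sets were chosen on parts of the share itself and their quartile ranges overlap, although the sort for c-Kit positive and Gr-1 negative cells should remove them.

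At day 8, 921 of 1195 calls were higher in the null. The share of higher calls was 63.1% or more whichever of the 4 day 8 arrays was left out, against 77.1% with all arrays. Such a fit leaves 1 array in a group, so this share does not decide what a single array contributed to the excess. The excess did not sit in dim or bright probe sets alone, since the share was 70.4%, 80.6% and 76.7% among the probe sets of lowest, middle and highest signal (3 bins of equal size). The share was 67.8% or more after quantile normalization, scaling to the same median and cyclic loess, and 47.0% when arrays were scaled to the hybridization controls. The latter decides nothing about the excess for the same reason (the controls were higher by 0.09 in the null, with an SD of 0.13 between wild-type replicates), so a shift of that size between the genotypes and an effect of the loss of miR-223 cannot be told apart.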

How the results depend on the processing

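Scaling to the hybridization controls and the fit of mouse control probe sets were chosen only after the results were seen. Of the 131 recomputed counts and correlations, 98 stayed within 1.5 times the value reported and no correlation changed sign. For null against wild type at day 8 (1195), the count was 694 after scaling to the hybridization controls, 747 without the intensity trend, 1998 at an adjusted p below 0.10, 443 with at least 1.5-fold change and 355 to 1691 when 1 array was left out, with 608, 355, 401 and 523 without wild-type replicate 1, null replicate 1, wild-type replicate 2 and null replicate 2 of day 8. For day 4 (613) it was 222 without the trend, 98 in a fit of only the groups compared, 1251 at an adjusted p below 0.10, 254 with at least 1.5-fold change and 129 to 1674 when 1 array was left out, with 217 and 1674 without wild-type day 4 replicate 1 and 2, 129 and 140 without null day 4 replicate 1 and 2, and 397 and 401 without null day 8 replicate 1 and 2. For the difference between the days (373) it was 211 after quantile normalization, 199 after cyclic loess, 124 after scaling to the hybridization controls, 129 without the trend, 971 at an adjusted p below 0.10 and 48 to 893 when 1 array was left out, the count being outside 1.5 times for every array except wild-type day 4 replicate 1 (250). With the filter at the 75th percentile, where fewer probe sets are tested, 9601 (wild type) and 9673 (null) were called from day 4 to day 8, and with no filter the null effects of the days correlated at 0.187. The labels do not say whether a replicate number stands for the same animals or cultures in different groups. Replicate differences correlated at -0.05 to 0.22 between groups, highest between null day 4 and null day 8, so a shared source is not excluded. With the replicate number as a block the counts were 1225, 630, 17467, 17151 and 319. Among named probe sets no called change turned, in 30 cases an alternative ended a call and in 23 it made 1 in the same direction. The change of 1427451_A_AT from day 4 to day 8 in wild type, not called as deposited (0.07), was called at -0.31 without wild-type day 4 replicate 2 and at 0.45 without replicate 1. Among the control transcripts, scaling to the hybridization controls turned beta-actin 3' to -0.16 and Gapdh 5' to -0.20 in null, and Gapdh 3' to -0.0171 and Gapdh middle to -0.0340 in wild type, from day 4 to day 8, and called Gapdh 3' at -0.26 and Gapdh middle at -0.25 in null, which were not called as deposited. The latter pair was called in the other direction after quantile normalization (0.15 and 0.19) and cyclic loess (0.27 and 0.29), and Gapdh middle also at 0.10 without either wild-type day 4 array. A looser threshold and a required fold change counts by construction, and leaving out an array also takes residual degrees of freedom away. The fit of only the groups compared had fewer residual degrees of freedom on both days, but its count was 1406 at day 8 against 98 at day 4. Fewer degrees of freedom alone therefore do not account for the 98. At day 4 that fit rests in part on wild-type day 4, the group with the widest replicate differences (SD 0.229). The cause of the other changes was not tested. Transcripts near the lower quartile of signal have folds limited by background. The gene lists, the seed sites, the pseudocounts and the combination of probe sets per gene were not run, for want of gene names, sequences and linear values.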

Other observations

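The test of maturation within a single genotype, with its repeats under the alternatives, was chosen only after the results were seen, while that over both genotypes was not.

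Transcripts called between the genotypes were compared with what they did from day 4 to day 8, the change being the mean of both genotypes. Of the 482 probe sets lower in the null at day 4, 47.7% rose by 2-fold or more with maturation, against a median of 15.4% in 10000 lists matched on mean signal (upper end of the central 95% of lists, 18.5%), and 7.88% fell by as much (matched median 21.4%). Of the 131 higher in the null at day 4, 42.7% fell by 2-fold or more (matched median 21.4%, upper end 28.2%). The chance errors of the wild-type day 4 arrays work against this relation when maturation is taken from wild type alone, and there the share that rose was still 44.0% (matched median 14.1%, upper end 17.2%). Over the other scalings it was 44.8% to 51.7%, and without any 1 array 43.8% to 66.0%, each above the upper end of lists matched to that alternative. The matched lists draw probe sets and not cultures, so they do not measure how far cultures of 1 genotype differ in stage. The alternatives reuse the same 8 arrays and add no independent support. Such shares would follow under the hypothesis that null progenitors at day 4 stood slightly earlier on the path to neutrophils, or held fewer cells that had started on it. With 2 arrays per group, a chance difference in stage between cultures cannot be told apart from it. Each of the wild-type day 4 arrays, at -84.2 and -95.1 on the first principal component, lay nearer to day 8 than both null arrays, at -98.6 and -100.5, but the wild-type arrays differed from each other by as much as the groups did, and wild-type cells that had passed the sort while maturing would give the same picture.

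At day 8 the matching hypothesis, that transcripts which fall during maturation stayed higher in the null, was less secure. Of the 921 probe sets higher in the null, 30.8% fell by 2-fold or more (matched median 21.7%, upper end 24.3%). But 17.6% of them rose by as much (matched median 15.2%, upper end 17.4%), so the excess was not confined to falling transcripts. Of the 274 lower in the null, 19.3% rose (upper end 19.0%) and 23.0% fell (upper end 25.9%). With maturation taken from null cells alone, where chance errors work against the relation, the share of the 921 that fell was 24.8% (upper end 24.0%). In 8 of 12 alternatives (4 scalings and 8 arrays left out) that share was not above the upper end of lists matched to that alternative. Fewer calls make shorter lists with a wider range, so this tally does not measure the strength of the relation alone. The share was 35.0% after scaling to the hybridization controls (matched median 30.1%, upper end 35.0%) and 25.7% without null day 8 replicate 1 (matched median 21.2%, upper end 26.0%). It was 24.4% after scaling to the same median (upper end 24.8%), 23.1% without either wild-type day 4 array (upper end 23.6%), 23.4% without null day 4 replicate 2 (upper end 24.7%), 21.5% without wild-type day 8 replicate 2 (upper end 26.4%) and 38.9% without wild-type day 8 replicate 1 (upper end 24.9%). Whether the loss of progenitor transcripts was delayed at day 8 stays open.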
